A study of Mus musculus with 8 samples.

How the data were processed

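Total RNA of sorted DP thymocytes was sequenced in 8 samples, 4 control and 4 Lck-cre, each group with 1 female and 3 males. Per the labels, RNA was purified with a column kit and sequenced by a commercial provider. Per the labels, the authors used HISAT and Bowtie2, whose versions and roles are not given in the sources used here, nor are the genome build, the annotation, the quantifier, the read length and the strandedness. The deposited tables, 1 per sample, give each gene's versioned Ensembl ID, symbol and position. Per the file headers, the authors computed FPKM, mapped fragments scaled by gene length and library size, whose sums differ between samples. The deposited TPM values, also computed by the authors, sum to 1000000 in each sample. The deposited coverage column gives the mean read coverage per base of each gene, not scaled by depth. Read counts are not in the tables used here.

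Each table held 55361 to 55366 entries for 55359 gene IDs, and values of entries that share an ID were summed. Of 52083 genes shared with the GRCm38 annotation, 2.87% had the same start and end, so positions are given as the files list them, with no build. Depth is unknown without counts. As a proxy, coverage was divided by FPKM, and the commonest ratio, which held in 36.8% to 38.1% of genes, was 7.53 to 7.89 across samples. Pearson correlations of log2 values between samples of the same group were 0.983 to 0.991 in Lck-cre and 0.985 to 0.992 in the controls, and at most 2 expressed genes had identical values in any pair of samples.

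The design fixed before the data were examined named a count-based test, to be replaced by limma on FPKM if no counts were found. The fallback was used, since the tables hold no counts. Genes with an FPKM of at least 1 in at least 4 samples were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with terms for sex and genotype and empirical Bayes moderation with a trend (prior degrees of freedom 4.17). A gene could meet this FPKM minimum through 1 group alone, as H2-Aa, Ly6a, Ier3 and Trgj1 did. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Summaries used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. Single measures were compared between groups by an exact two-sided permutation test of the means over all 70 assignments, whose smallest p is 0.0286. Folds are ratios of mean FPKM, errors of levels are SDs over 4 samples, and SEs and intervals are those of limma.

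Gene lists were also fixed before the data were examined: 27 lists with 723 entries, of which 717 matched by symbol, 3 by gene ID and 1 by an older symbol, and 2 (Ctsv and Ahsp) were not found. Where genes shared a symbol, the gene with the highest mean was taken. The 21 lists with at least 5 tested members were tested with limma's camera against the other tested genes, with a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the lists. Counts adjusted over the list alone used the same p-values, adjusted over the tested members of the list. The lists overlap, so Egr1, Btg2, Bax and Ptcra, among others, stand in more than 1.

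Named genes followed a rule fixed at the same time. It took Sting1, sex-linked genes as a check of the labels, 16 genes given whatever their result, the 10 largest increases and the 10 largest decreases, and up to 4 members of each list. The largest changes were taken among called genes with a mean FPKM of at least 1 in the higher group, no overlap between groups and a symbol other than that of a predicted gene. List members were the 2 that rose and the 2 that fell with the smallest adjusted p, or, where none passed, the 1 with the smallest p. The rule named 94 genes, of which 91 were tested and 79 were called. The TCR alpha segments as a group were chosen after their values were seen.

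On simulated data with the spread of these samples and independent genes, the fit recovered 80% of genes raised by 0.58 (log2), 92.5% raised by 1 and 100% raised by 2, and called 8 of 12107 unchanged genes. The changed genes were drawn from those with a fitted level above 2 (log2), so recovery near the filter was not measured. Camera called the shifted list and 0 of 20 unshifted lists. The simulated genes were independent, while the estimated correlation in the real lists reached 0.895, so this does not show how camera behaves on correlated lists.

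Alternatives planned before the data were examined were quantile normalization, pseudocounts of 0.1 and 1, no filter, a filter on a mean FPKM of at least 1, no sex term, males only, each sample left out in turn, an adjusted p under 0.01, and a fold of at least 2 by limma's treat. TPM in place of FPKM and median-of-ratios scaling of FPKM were added after the data were seen. The planned count-based tests were not run, since there were no counts. Without either female the sex term leaves the other female uninformative, so that setting compares 3 males with 3 males. The 35 splits of the samples into 4 and 4 were refitted with the same terms. All samples and genes with values were used, and the labels give no batch.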

Results

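RNA sequencing measured gene expression in 8 samples of mouse thymocytes at 5 weeks of age. The cells were sorted for CD4 and CD8 together (the double positive, or DP, stage) and for absent to intermediate surface TCR beta. All samples carried LSL-Sting1-N153S, in which a stop cassette between loxP sites precedes a coding sequence of STING with the N153S substitution, known as a gain-of-function change. The 4 control samples (replicates 1 to 4) lacked Cre, and the 4 Lck-cre samples (replicates 5 to 8) also carried Cre recombinase under the Lck promoter, which is active in T cell progenitors. Each group held 1 female (replicates 1 and 5) and 3 males. Whether each sample came from a separate animal is not given in the sources used here, so p-values measure the spread between samples.

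The tables listed 55359 genes, of which 22809 to 23443 per sample had an FPKM above 0 and 12177 to 12342 had an FPKM of at least 1. Read counts are not given in the sources used here, so the total depth is unknown. In the genes with the commonest ratio, 1 FPKM stood for a per-base coverage of 7.53 to 7.89 in the controls and 7.65 to 7.86 in the Lck-cre samples. The FPKM sum was 413835 to 437426 in the controls and 437778 to 457145 in the Lck-cre samples. Xist, transcribed from the inactive X chromosome, lay at 51.7 to 62.0 FPKM in the 2 females and at 0.0369 to 0.170 in the 6 males. The Y-linked gene Ddx3y lay at 30.2 to 39.4 FPKM in the males and at 0.0111 to 0.197 in the females. Eif2s3y reached 0.503 FPKM at most in the females and was at least 39.0 in the males. The highest female values were 0.0829 FPKM for Kdm5d and 0.0440 for Uty, against lowest male values of 9.14 and 5.97.

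The first comparison asked whether Sting1 transcripts differed between Lck-cre and control DP thymocytes, as a check of the labels. Sting1, the endoplasmic reticulum receptor for cyclic dinucleotides, rose from 13.1 ± 1.70 FPKM in the controls to 167 ± 71.2 FPKM in the Lck-cre samples (SD, n = 4 each), a 12.8-fold difference between means. The controls lay at 15.3, 11.6, 13.4 and 11.9 FPKM, and the Lck-cre samples at 221, 85.4, 130 and 232 FPKM in the order of replicates 5 to 8. The gene is listed as ENSMUSG00000024349.11 on the minus strand of chromosome 18 from 35866732 to 35873607, in a genome build that the files do not name. The log2 change was 3.52 (SE 0.25, 95% confidence interval 2.95 to 4.09, adjusted p = 0.00213 by limma). The exact two-sided permutation test of the means gave p = 0.0286, the smallest that 4 against 4 samples allow. Mean coverage per base of Sting1 was 63.3 to 91.1 in the controls and 532 to 1141 in the Lck-cre samples. FPKM values do not tell the mutant from the wild-type allele.

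**Figure D1:**
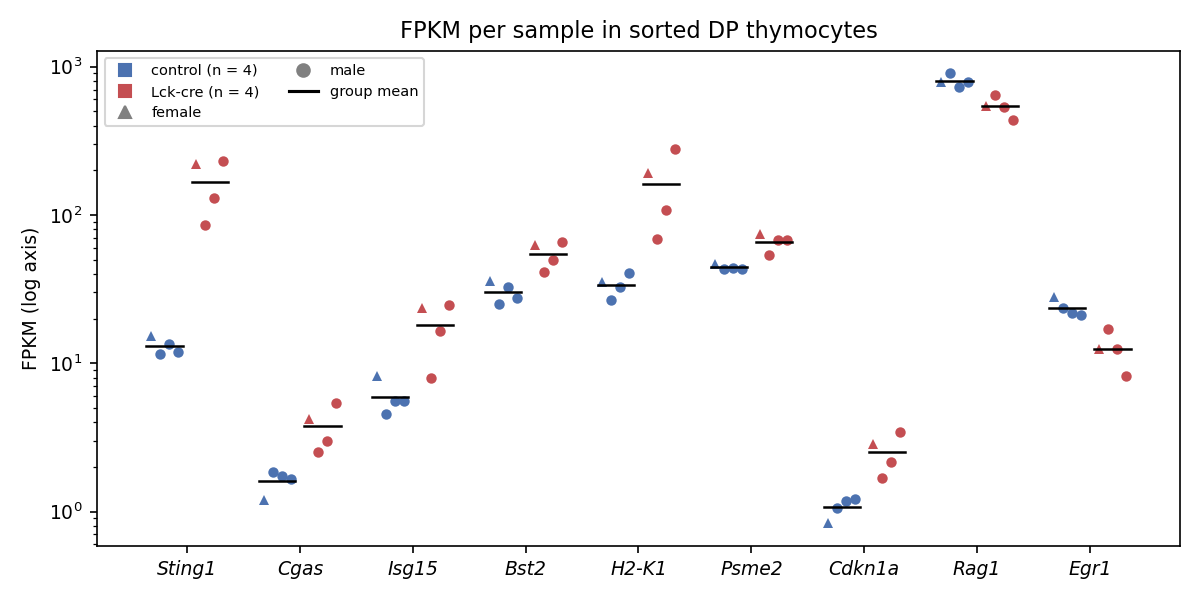
FPKM per sample (log axis) of 9 genes in control (blue, n = 4) and Lck-cre (red, n = 4) DP thymocytes. Triangles are females, circles are males and black lines are group means. Sting1 sits between 11.6 and 15.3 in the controls and between 85.4 and 232 in the Lck-cre samples, and the groups overlap for Isg15.

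The second comparison asked which other transcripts differed between the genotypes. In the Lck-cre samples 31 of 32 S phase, 31 of 34 G2/M and 29 of 42 ribosomal protein genes rose, as did the MHC class I gene H2-K1, while Rag1 and the TCR response genes Egr1 and Nab2 fell. Each of these 3 lists had adjusted p = 0.388 in camera with an estimated correlation, and the calls of these 4 genes ended with no filter (adjusted p of 0.0526 for H2-K1, 0.0674 for Rag1, 0.0607 for Egr1 and 0.0526 for Nab2). Besides Sting1, the 9 largest increases under the rule for named genes were Plac8, Trgc2, Trgj2, Tesc, Trgv2, Trgc1, Ier3, Ly6a and Trgj1, with log2 changes of 2.85, 2.51, 2.50, 2.45, 2.29, 2.13, 2.10, 2.08 and 2.07. Plac8 rose from 1.06 ± 0.183 to 12.2 ± 6.38 FPKM, and Tesc, a calcium-binding protein, rose from 1.07 ± 0.187 to 8.66 ± 3.79 FPKM (SD, n = 4 each). Of the 10 largest decreases, 8 were gene segments of the TCR alpha chain, and the other 2 were Cacna1e, a voltage-gated calcium channel subunit, and Smoc1, a secreted matrix protein. Cacna1e fell from 7.74 ± 2.74 to 1.59 ± 0.921 FPKM and Smoc1 from 21.1 ± 2.86 to 7.29 ± 4.22 FPKM.

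Of 12337 genes tested with limma, 3180 (25.8%) passed an adjusted p of 0.05, of which 1901 rose and 1279 fell in Lck-cre. The counts of called list members that follow are to be read against this share. The median size of the log2 change among these was 0.413, and 140 changed by over 2-fold, 63 up and 77 down. The groups did not overlap in 3627 genes (29.4%), against the 2.86% that chance gives. On the first principal component, with 52.7% of the variance, the controls lay at -23.43 to -12.84 and Lck-cre replicates 5 to 8 at 19.23, 3.53, 17.89 and 31.11. TPM values in place of FPKM gave 1300 genes up and 2067 down, so the balance between directions turned with the scaling. Without 1 sample the count was 653, 1256, 3009 or 2111 (control replicates 1 to 4), or 647, 3889, 1802 or 2079 (Lck-cre replicates 5 to 8).

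**Figure D2:**
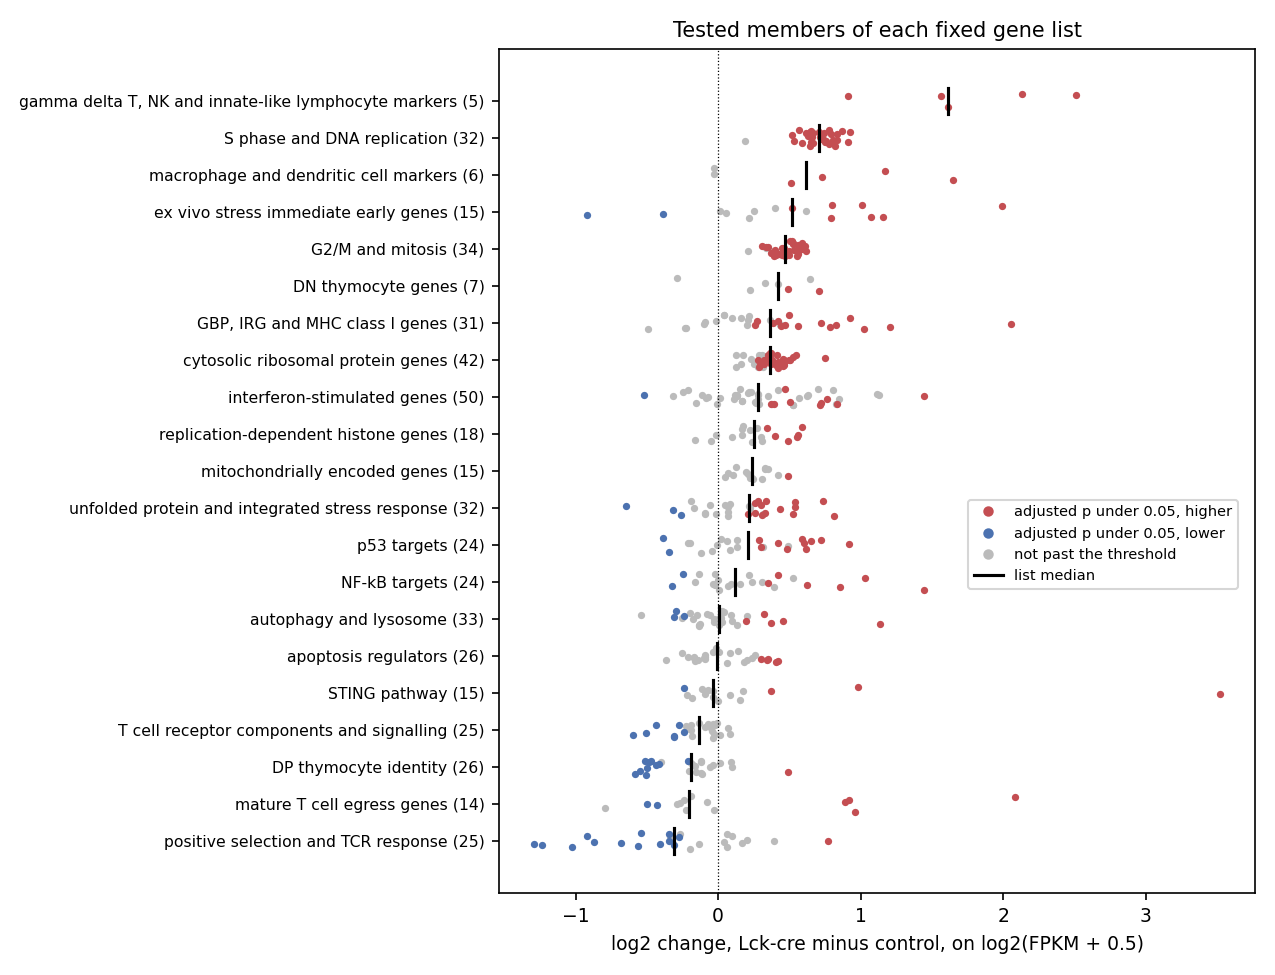
The log2 change (Lck-cre minus control, on FPKM plus 0.5) of each tested member of the 21 lists with at least 5 tested members, with that number in parentheses. Points are genes, coloured by the limma call, and black lines are list medians. The S phase median lies at 0.71 and that of positive selection genes at -0.31.

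Among STING pathway genes, Sting1 itself included, 3 of 15 tested rose and 1 fell, the same counts as when adjusted over the list alone, and with TPM values 3 rose and 2 fell. Cgas, the DNA sensor that makes cyclic GMP-AMP, rose from 1.61 ± 0.285 to 3.78 ± 1.29 FPKM (log2 change 0.98, SE 0.21, n = 4 each). Irf3, a transcription factor activated through STING, fell from 108 ± 2.91 to 92.0 ± 8.83 FPKM (log2 change -0.24, SE 0.08). Tbk1, the kinase of Irf3, lay at 21.5 ± 1.01 and 20.5 ± 1.2 FPKM (adjusted p = 0.468 by limma). The list as a whole did not pass limma's camera (adjusted p = 0.698), and its median of -0.037 and mean of 0.286, both with Sting1 included, had opposite signs. The calls of Cgas and Irf3 ended without either female (adjusted p of 0.0637 and 0.0648 for Cgas, 0.174 for Irf3), and that of Irf3 also without control replicates 2, 3 or 4 or Lck-cre replicates 7 or 8 (0.0682 to 0.113).

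Among interferon-stimulated genes, 9 of 50 tested rose and 1 fell, or 14 and 3 adjusted over the list alone, and with TPM values 8 rose and 3 fell. Of all tested genes 25.8% passed, so the count of 9 and 1 does not by itself set this list apart. Bst2, a membrane protein that tethers budding viruses, rose 1.80-fold from 30.4 ± 4.83 to 54.8 ± 11.3 FPKM, and Epsti1 rose 1.70-fold from 61.4 ± 7.24 to 105 ± 13.6 FPKM (SD, n = 4 each). Isg15, a ubiquitin-like modifier, rose from 5.96 ± 1.57 to 18.2 ± 7.76 FPKM with overlapping groups, and Ifi209 fell from 24.5 ± 5.39 to 16.6 ± 0.748 FPKM. Irf7 lay at 4.91 ± 1.46 and 7.38 ± 2.35 FPKM (adjusted p = 0.0747 by limma), and passed only without Lck-cre replicate 6 (adjusted p = 0.0142). Ifit1 lay below the filter, at 0.408 ± 0.189 and 1.63 ± 1.21 FPKM. The list passed camera (adjusted p = 0.00057), with adjusted p = 0.522 with an estimated correlation. The calls of Isg15 and Ifi209 ended without either female (adjusted p of 0.0502 and 0.0506 for Isg15, 0.0695 and 0.0693 for Ifi209), and that of Ifi209 without control replicate 2 (0.0504).

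Of GBP, IRG and MHC class I genes, 15 of 31 tested rose and 0 fell by limma, or 21 and 3 adjusted over the list alone, with TPM values 11 rose and 3 fell. H2-K1, a classical MHC class I heavy chain, rose 4.75-fold from 33.9 ± 5.81 to 161 ± 92.7 FPKM (log2 change 2.05, SE 0.36). Psme2, a subunit of the proteasome activator, rose 1.49-fold from 44.2 ± 1.81 to 65.8 ± 8.90 FPKM. The list passed camera (adjusted p = 0.000378), with adjusted p = 0.388 with an estimated correlation. Reads of H2-K1 can be shared with other class I genes of near-identical sequence. Of interferon ligands and receptors, 4 were tested and Ifnar2, a chain of the type I interferon receptor, rose from 20.7 ± 0.391 to 25.4 ± 2.27 FPKM, a call of limma that ended with TPM values (adjusted p = 0.0675) and without control replicates 1 or 2 or Lck-cre replicates 5, 7 or 8 (0.0589 to 0.104). Adjusted over the list alone, Ifnar2 again was the 1 gene that rose, with TPM values 0 rose and 1 fell by limma, and Ifnb1, the gene of interferon beta, was listed at 0 in all 8 samples.

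NF-kB targets divided, with 6 of 24 tested rising and 2 falling, as when adjusted over the list alone. Ltb, or lymphotoxin beta, rose 1.54-fold from 124 ± 12.9 to 192 ± 18.7 FPKM, and Relb, a subunit of NF-kB, rose 1.95-fold from 3.25 ± 0.214 to 6.34 ± 1.17 FPKM (SD, n = 4 each). Cflar, an inhibitor of caspase 8, fell from 30.9 ± 2.40 to 24.6 ± 2.02 FPKM, and Birc2, a ubiquitin ligase of TNF receptor signalling, fell from 35.1 ± 2.22 to 29.5 ± 1.72 FPKM. The list passed camera (adjusted p = 0.038), with adjusted p = 0.461 with an estimated correlation, and missed the threshold without control replicate 3 (0.104) or Lck-cre replicate 8 (0.0765). Of the stress-induced immediate early genes, 7 of 15 rose and 2 fell, or 8 and 2 adjusted over the list alone. Junb, an AP-1 subunit, rose 2.28-fold from 53.4 ± 10.3 to 122 ± 35.9 FPKM and Ier2 rose 1.78-fold from 20.7 ± 2.08 to 36.9 ± 8.35 FPKM. This list passed camera (adjusted p = 0.00694), with adjusted p = 0.388 with an estimated correlation.

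Replication and mitosis genes rose nearly throughout. Of 32 S phase genes, 31 rose and 0 fell by limma, and all 32 passed when adjusted over the list alone, with a median log2 change of 0.709. Tyms, or thymidylate synthase, rose 1.68-fold from 23.7 ± 2.60 to 39.8 ± 4.42 FPKM, and Ccne1, the cyclin of the G1 to S transition, rose 1.72-fold from 14.2 ± 1.25 to 24.5 ± 3.26 FPKM (SD, n = 4 each). Of 34 G2/M genes, 31 rose and 0 fell by limma, or 32 and 0 adjusted over the list alone, with a median of 0.466. Ndc80, a kinetochore protein, rose 1.49-fold from 17.5 ± 2.07 to 26.1 ± 3.17 FPKM, and Aurkb, a mitotic kinase, rose 1.51-fold from 59.1 ± 7.27 to 89.0 ± 10.8 FPKM. The lists passed camera (adjusted p = 1.74e-16 and 2.34e-13), with adjusted p = 0.388 with an estimated correlation for both.

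Of cytosolic ribosomal protein genes, 29 of 42 rose and 0 fell by limma, or 38 and 0 adjusted over the list alone. The median log2 change was 0.364, and 0.230 with quantile normalization, under which 18 rose. Rps2 rose 1.70-fold from 339 ± 15.9 to 574 ± 106 FPKM and Rpl14 rose 1.46-fold from 119 ± 12.1 to 175 ± 16 FPKM. Camera gave adjusted p = 2.95e-11 for this list, with adjusted p = 0.388 with an estimated correlation. Replication-dependent histone genes rose in 6 of 18 cases and fell in 0 by limma, as when adjusted over the list alone, and with TPM values 3 rose. Among the 6 were H4c9 (12.7 ± 0.863 to 19.7 ± 4.43 FPKM) and H2ac8 (3.62 ± 0.568 to 5.52 ± 0.475 FPKM). That list passed camera (adjusted p = 0.00808), with adjusted p = 0.388 with an estimated correlation. Among mitochondrially encoded genes, mt-Rnr1, the small ribosomal RNA, rose from 146 ± 15.3 to 204 ± 13.3 FPKM, the 1 call among 15 genes, as when adjusted over the list alone. Camera gave adjusted p = 0.00808, with adjusted p = 0.464 with an estimated correlation, and the call ended with quantile normalization (0.228).

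Among genes that define the DP stage, 10 of 26 fell and 1 rose, as when adjusted over the list alone. Rag1, which cleaves DNA in antigen receptor gene rearrangement, fell from 802 ± 71.4 to 538 ± 86.2 FPKM (log2 change -0.59, SE 0.13), and Cd4 fell from 747 ± 36.4 to 545 ± 111 FPKM (log2 change -0.47, SE 0.14). Tespa1 fell from 63.5 ± 6.34 to 47.4 ± 1.48 FPKM and Bcl6, a transcriptional repressor, from 76.2 ± 4.28 to 54.6 ± 8.20 FPKM, while Ptcra, the pre-TCR alpha chain, rose from 29.9 ± 3.49 to 42.4 ± 6.34 FPKM (SD, n = 4 each). Cd8a lay at 1147 ± 67.1 and 1029 ± 120 FPKM (adjusted p = 0.274 by limma). Camera called the list lower (adjusted p = 0.000262), with adjusted p = 0.388 with an estimated correlation. The calls of Rag1, Bcl6 and Ptcra ended without control replicate 1 (adjusted p of 0.0572, 0.0613 and 0.0512) and without Lck-cre replicate 5 (0.0579, 0.0615 and 0.0517), and that of Cd4 ended whenever a sample other than Lck-cre replicate 6 was left out, with adjusted p of 0.0609 to 0.131.

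Of positive selection and TCR response genes, 13 of 25 fell and 1 rose, as when adjusted over the list alone. Egr1, a transcription factor induced by TCR signals, fell from 23.5 ± 3.06 to 12.5 ± 3.63 FPKM (log2 change -0.92, SE 0.18), and its co-repressor Nab2 fell from 26.0 ± 4.40 to 12.7 ± 3.34 FPKM (log2 change -1.02, SE 0.19). Cd5, an inhibitor of TCR signals, fell from 139 ± 15.7 to 105 ± 16.3 FPKM, and Runx3, a transcription factor of the CD8 lineage, rose from 4.45 ± 0.512 to 8.09 ± 2.04 FPKM (SD, n = 4 each). Cd69 lay at 15.2 ± 1.55 and 20.7 ± 5.94 FPKM (adjusted p = 0.0972 by limma), and passed without Lck-cre replicate 6 (adjusted p = 0.0464). Camera called the list lower (adjusted p = 0.000577), with adjusted p = 0.388 with an estimated correlation. In the same samples Junb and Ier2, immediate early genes like Egr1, rose. The calls of Egr1, Runx3 and Cd5 ended without control replicate 1 (adjusted p of 0.0556, 0.0617 and 0.133) and without Lck-cre replicate 5 (0.0556, 0.0624 and 0.134), and that of Cd5 also without control replicate 2 (0.0806) or 4 (0.0665) or Lck-cre replicate 8 (0.0564).

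TCR components and signalling genes fell in 7 of 25 cases and rose in 0 by limma, as when adjusted over the list alone. Fyn, a Src family kinase, fell from 47.3 ± 3.72 to 35 ± 4.71 FPKM, and Plcg1, a phospholipase of the TCR pathway, fell from 112 ± 10.9 to 90.0 ± 5.31 FPKM. Camera called the list lower (adjusted p = 0.00214), with adjusted p = 0.388 with an estimated correlation. Among genes of mature T cells that leave the thymus, 4 of 14 rose and 2 fell, or 4 and 4 adjusted over the list alone, and with TPM values 4 rose and 6 fell. Ly6a rose from 0.695 ± 0.174 to 5.52 ± 4.17 FPKM, the integrin chain Itgb7 rose from 11.5 ± 3.58 to 23.3 ± 8.17 FPKM with overlapping groups, Klf3 fell from 70.4 ± 5.63 to 50.0 ± 7.54 FPKM and Ms4a6b fell from 15.1 ± 2.59 to 11 ± 1.11 FPKM. That list did not pass limma's camera (adjusted p = 0.293), and its median of -0.206 and mean of 0.129 had opposite signs. Of double negative stage genes, 2 of 7 rose and 0 fell by limma, or 6 and 1 adjusted over the list alone: Ptcra and Dtx1, a Notch target, which rose from 4.23 ± 1.04 to 7.33 ± 2.32 FPKM. This list passed camera (adjusted p = 0.0257), with adjusted p = 0.388 with an estimated correlation, and missed the threshold with no sex term (0.0613).

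Of p53 targets, 10 of 24 rose and 2 fell, or 11 and 3 adjusted over the list alone, and with TPM values 8 rose and 4 fell. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose 2.36-fold from 1.07 ± 0.171 to 2.53 ± 0.765 FPKM, and Bax, an effector of apoptosis, rose 1.34-fold from 50.9 ± 3.13 to 68.2 ± 4.09 FPKM (SD, n = 4 each). Psrc1, a spindle protein, rose from 13 ± 0.697 to 18.4 ± 2.10 FPKM, while Sesn1 fell from 37.1 ± 4.62 to 29.0 ± 2.74 FPKM and Btg2, also among the immediate early genes, from 194 ± 19.6 to 149 ± 22.3 FPKM. The list passed camera (adjusted p = 0.0224), with adjusted p = 0.388 with an estimated correlation, and missed the threshold without control replicate 3 (0.0514). Of apoptosis regulators, 5 of 26 rose and 0 fell by limma, as when adjusted over the list alone, with TPM values 4 rose and 3 fell. Bid rose from 20 ± 0.920 to 26.7 ± 2.20 FPKM, and Bcl2, an inhibitor of apoptosis, lay at 2.41 ± 0.185 and 2.24 ± 0.385 FPKM (adjusted p = 0.499 by limma). That list did not pass limma's camera (adjusted p = 0.698), and its median of -0.006 and mean of 0.041 had opposite signs. The call of Cdkn1a ended without either female (adjusted p of 0.0591 and 0.0606).

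Of genes of the unfolded protein and integrated stress responses, 14 of 32 rose and 3 fell, or 16 and 3 adjusted over the list alone. Phgdh and Psat1, enzymes of serine synthesis, rose 1.77-fold and 1.68-fold, from 61.5 ± 6.88 to 109 ± 16.9 FPKM and from 17.5 ± 2.52 to 29.4 ± 3.42 FPKM. Xbp1 and Eif2ak3, both mediators of the unfolded protein response, fell from 79.5 ± 4.91 to 63.8 ± 4.75 FPKM and from 38.3 ± 3.10 to 31.8 ± 1.87 FPKM. Ddit3, a transcription factor of the same responses, lay at 16.8 ± 1.49 and 17.8 ± 2.14 FPKM (adjusted p = 0.61 by limma). The list passed camera (adjusted p = 0.0079), with adjusted p = 0.388 with an estimated correlation. Of autophagy and lysosome genes, 5 of 33 rose and 3 fell, as when adjusted over the list alone, and with TPM values 3 rose and 8 fell. Tfeb, a transcription factor of lysosomal genes, rose 2.55-fold from 2.19 ± 0.147 to 5.58 ± 1.77 FPKM and the proton pump subunit Atp6v1h from 18.9 ± 0.851 to 23.7 ± 1.06 FPKM, while the autophagy genes Ulk1 and Atg9a fell from 46.1 ± 3.71 to 37.4 ± 2.64 FPKM and from 21.6 ± 1.5 to 17.4 ± 1.98 FPKM. That list did not pass limma's camera (adjusted p = 0.646, lower), though its median of 0.003 and mean of 0.013 were above 0.

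Markers of gamma delta T, NK and innate-like lymphocytes rose in all 5 tested cases, as when adjusted over the list alone. Trgc2, a TCR gamma constant gene, rose from 1.59 ± 0.847 to 11.9 ± 5.70 FPKM, and Trdc, the TCR delta constant gene, rose 1.92-fold from 27.2 ± 1.05 to 52.2 ± 9.05 FPKM (SD, n = 4 each). This list passed camera (adjusted p = 0.000151), with adjusted p = 0.388 with an estimated correlation. Of macrophage and dendritic cell markers, 4 of 6 tested rose and 0 fell by limma, as when adjusted over the list alone. In the controls H2-Aa reached at most 0.509 FPKM and Cd74 at most 1.01 FPKM, so both passed the filter through their Lck-cre values. Their being tested and their rise are thus not independent. Cd74, the MHC class II invariant chain, rose from 0.874 ± 0.10 to 4.10 ± 1.83 FPKM and H2-Aa, an MHC class II chain, from 0.379 ± 0.109 to 1.55 ± 0.684 FPKM, in the same samples in which Bst2, Epsti1 and H2-K1 rose. That list passed camera (adjusted p = 0.0224), with adjusted p = 0.388 with an estimated correlation, and missed the threshold under the filter on mean FPKM (0.0744).

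Of B cell markers, 3 of 4 tested rose, as when adjusted over the list alone, among them Ighm (403 ± 20.6 to 505 ± 27.3 FPKM), a call of limma that ended with quantile normalization (adjusted p = 0.145), and Cd72 (0.917 ± 0.134 to 2.19 ± 0.746 FPKM). Cd72 lay at 0.798 to 1.06 FPKM in the controls, so it too passed the filter through its Lck-cre values. Hemgn, the 1 erythroid marker tested, rose from 3.81 ± 0.597 to 8.34 ± 1.22 FPKM, also when adjusted over the list alone. By limma 0 of 4 thymic epithelial and 0 of 2 endothelial and mesenchymal markers passed, also when adjusted over the list alone, though 1 thymic epithelial marker fell with TPM values, with the smallest p for Ly75 (3.53 ± 0.295 and 4.84 ± 1.23 FPKM, adjusted p = 0.0827) and Pecam1 (48.5 ± 3.89 and 53.5 ± 3.47 FPKM, adjusted p = 0.163). With no filter, camera called the thymic epithelial (adjusted p = 0.0038, 15 members) and erythroid (adjusted p = 0.0222, 9 members) lists higher, and the B cell (0.0845), neutrophil (0.0845) and endothelial and mesenchymal (0.0561) lists missed the threshold. An estimated correlation was not run with no filter. Of 15 thymic epithelial markers 4, Krt8, Aire, Prss16 and Tbata, were higher in all 4 Lck-cre samples than in all 4 controls and 0 were lower, where chance gives 0.21. Among all tested genes 29.4% did not overlap, in either direction, a share that this 0.21 does not take into account. These 4 markers lay below the filter, where that share was not computed. Of 13 neutrophil markers 0 reached the filter, and their highest Lck-cre mean was 0.0515 FPKM. In all, 17 of the 21 lists tested passed camera with its preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.388. Fry, which tests whether a list moves one way on balance without comparing it with other genes, called 12 lists. These included the STING pathway (adjusted p = 0.0107), a list that holds Sting1 and was not tested without it. The lists of interferon-stimulated (0.123), NF-kB (0.0504), immediate early (0.0504), DP stage (0.0611), TCR signalling (0.071) and mitochondrial (0.104) genes missed its threshold.

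Gene segments of the TCR alpha chain, which lies on chromosome 14, were grouped after their values were seen. Of the 49 J alpha segments tested 20 fell and 4 rose, and of 110 V alpha segments 67 fell and 4 rose. Some V alpha segments had nearly the same values in each sample. Trav11d and Trav11 lay at 2.69 and 2.77 FPKM in control replicate 1, and at 1.21 and 1.29 FPKM in Lck-cre replicate 8. If such segments share reads, the count of 67 holds the same signal more than once, which was not tested. Of the 10 V alpha segments with dv in their symbols, for use with the delta chain as well, 4 rose and 3 fell. Those that rose were Trav15d-1-dv6d-1, Trav15-1-dv6-1, Trav15-2-dv6-2 and Trav13-4-dv7. Trav15n-1 and Trav15n-2, alike in name but without dv, had log2 changes of 0.41 and 0.26 (adjusted p of 0.0566 and 0.198 by limma). The symbol thus does not cleanly split the changes. Of the 100 without dv, both of these included, 0 rose and 64 fell by limma. Trac, the constant gene of the alpha chain, chosen after its values were seen, fell too, from 524 ± 35.4 to 352 ± 81.7 FPKM (log2 change -0.60, SE 0.15, adjusted p = 0.0223 by limma), a call that ended without either female (adjusted p of 0.0983 and 0.0996), without control replicate 2 (0.0597), with males alone (0.099) and with no filter (0.0936). Traj9 fell from 8.36 ± 2.15 to 0.863 ± 0.381 FPKM (log2 change -2.71, SE 0.23, adjusted p = 0.00366 by limma) and Trav1 from 7.58 ± 0.584 to 2.33 ± 1.40 FPKM (log2 change -1.67, SE 0.33, adjusted p = 0.0119). The others among the 10 largest decreases were Traj26, Traj11, Traj6, Traj30, Traj24 and Traj22, with log2 changes of -1.94, -1.84, -1.79, -1.75, -1.67 and -1.64. Of 25 V and C genes of the TCR beta chain, 0 rose and 0 fell by limma, with a median log2 change of -0.031. The J alpha segments measured 29 to 72 bases, and the call of Traj22 ended with a pseudocount of 0.1 (adjusted p = 0.0515).

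**Figure D3:**
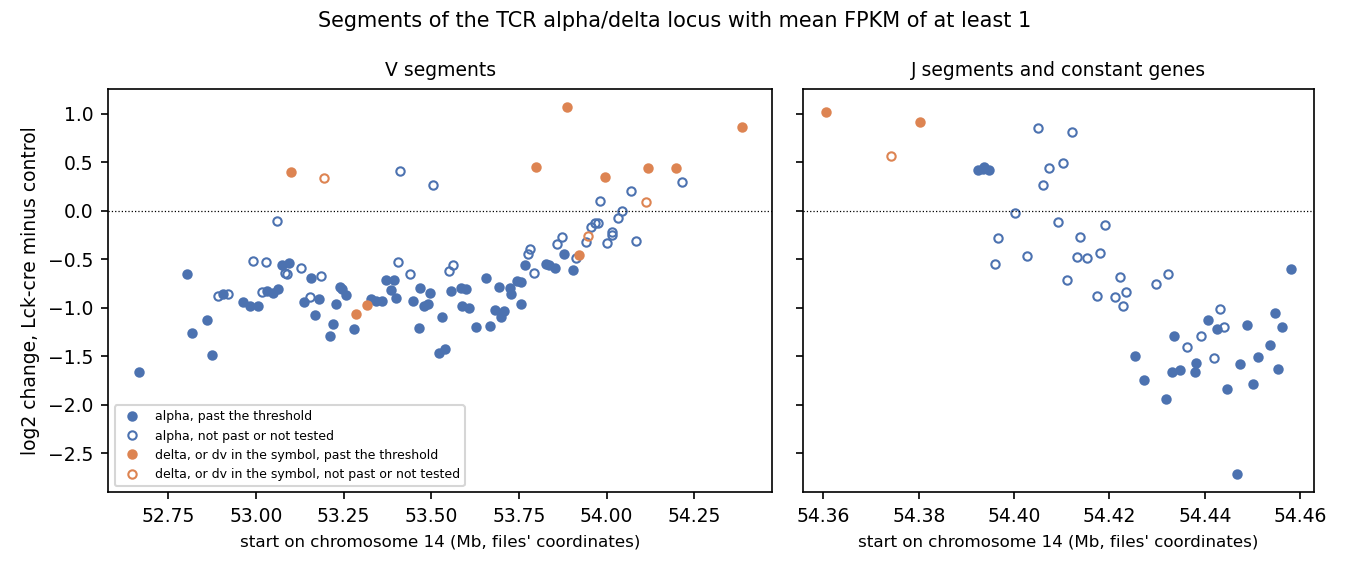
The log2 change (Lck-cre minus control) of gene segments of the TCR alpha and delta locus with a mean FPKM of at least 1, against their start on chromosome 14 in megabases. Filled points passed the limma threshold, blue points are alpha segments, and orange points are delta genes or segments with dv in the symbol. The J alpha points right of the middle of the cluster lie lower as a group than those left of it (medians of -1.46 and -0.277). Traj9 lies lowest, at -2.71, and the points at the far right end are not the lowest.

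Of the 79 calls among the named genes, 31 besides that of Sting1 held under every scaling, pseudocount, filter and sex setting and without any single sample. In the test for a fold above 2, Sting1 was the 1 gene called. Males alone and the absence of a filter ended 38 calls each, and 0 calls by limma changed direction under any setting. The calls of H2-K1, Nab2, Itgb7, H4c9, Cacna1e, Traj11 and Traj6 ended only with no filter (adjusted p of 0.0511 to 0.0637). No filter also ended those of Cgas, Irf3, Ifi209, Isg15, Ifnar2, Birc2, Sesn1, Btg2, Ulk1, Atg9a, Bcl6, Fyn, Plcg1, Runx3, Egr1, Ly6a, Klf3, Ms4a6b, Cd72, Ighm, H2ac8, Cd4, Rag1, Cd5, Cdkn1a, Trgj1, Traj26, Trav1, Traj24, Traj22 and Smoc1 (0.0526 to 0.149). Males alone ended the calls that ended without either female. Leaving out either female ended the calls of Cflar, Psrc1, Bid, Xbp1, Eif2ak3, Atp6v1h, Fyn, Ly6a, Klf3, Cd72, mt-Rnr1, H2ac8, Trgj1, Trav1 and Smoc1 (adjusted p of 0.0511 to 0.0806), and leaving out Lck-cre replicate 5 ended that of Dtx1 (0.0501). Leaving out control replicate 2 ended that of Traj24 (0.0516). For Birc2, Sesn1, Btg2, Ulk1, Atg9a, Plcg1, Ms4a6b, Ighm, Traj26 and Traj22, each female and at least 1 male, control replicate 2 among them, ended the call when left out, with adjusted p of 0.0511 to 0.128.

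The third comparison asked whether the effect of genotype differed between females and males. With 1 female per genotype, limma called 0 of 12337 genes for the interaction of sex and genotype, with a smallest adjusted p of 0.391 and 336 genes at an unadjusted p under 0.05. With no filter 306 of 28851 genes passed, and no other tool was run. The spread of the lone female in each group was taken to equal that of the males.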

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

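The comparison of each sample with the rest of its group was planned, and no explanation was tested for these values. Among the genes taken by the rule for named genes, 188 groups of 4 samples were examined for a highest or lowest sample far from the others, and 10 stood apart, where chance alone gives about 1 in 20 groups, or 9.4. Genes named in the text outside that rule, such as Trac and Cxcl10, were not examined. Of the 10, 6 follow the sex in the labels: Xist at 62.0 FPKM in control replicate 1 and 51.7 FPKM in Lck-cre replicate 5, Eif2s3y at 0.0277 and 0.503 FPKM, and Kdm5d at 0.0228 and 0.0829 FPKM in the same samples, the female of each group.

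The other 4 were in controls. Xbp1, a transcription factor of the unfolded protein response, lay at 86.9 FPKM in control replicate 1, with the nearest other control at 77.6. Cd5, an inhibitor of TCR signals, lay at 162 FPKM in the same sample, with the nearest at 133. Rpl14 lay at 137 FPKM in control replicate 3, with the nearest at 114, and Smoc1 at 16.8 FPKM in control replicate 4, with the nearest at 22.1. Chance flags about 1 in 20 groups, so these 4 values call for no explanation of their own. Without control replicate 1 the calls of Xbp1 (adjusted p = 0.063 by limma) and Cd5 (adjusted p = 0.133 by limma) ended, and that of Rpl14 held whichever sample was left out. The calls of Xbp1 and Cd5 also ended without Lck-cre replicate 5. Either setting compares 3 males with 3 males, so their end cannot be laid to the values of control replicate 1.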

How the results depend on the processing

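TPM values, median-of-ratios scaling and the quantile setting of the sex interaction were chosen after the data were seen, and the other alternatives were planned. Sting1 stayed past the threshold and higher in Lck-cre in every setting, with log2 changes of 3.27 to 3.78 when 1 sample was left out. Of 3180 genes called changed, 2889 were called again in the same direction with quantile normalization, 2579 with TPM values and 2969 with median-of-ratios scaling, and 0 by limma changed direction in any setting run. With no filter 1056 genes passed, 696 up and 360 down, among 28851 tested, and the cause was not tested. Males alone gave 652 genes, 425 up and 227 down, with fewer samples. Leaving out 1 sample gave 647 to 3889 genes, 419 to 2215 up and 226 to 1674 down. The lowest counts came without Lck-cre replicate 5 (647) and control replicate 1 (653), where 3 males were compared with 3 males, and the highest without Lck-cre replicate 6. Without control replicates 2 or 4 or Lck-cre replicates 7 or 8 the counts were 1256, 2111, 1802 and 2079, and the cause was not tested. An adjusted p under 0.01 left 512 genes, 384 up and 128 down, and a test for a fold above 2 left 1, Sting1, 1 up and 0 down, both stricter thresholds. TPM values gave 2067 genes down in place of 1279, since division by the FPKM sum, higher in the Lck-cre samples, moved the median log2 change by -0.071. The interaction of sex and genotype went from 0 genes by limma to 306 with no filter, and the cause was not tested. Gene lists called by camera numbered 17, 15 to 17 without 1 sample, 19 of 27 with no filter, 12 by fry, and 0 by limma's camera with an estimated correlation. Among the 17 called lists the estimated correlation ran from 0.022 (double negative stage genes) to 0.895 (gamma delta list), and was 0.82 for S phase genes. All lay above the preset 0.01, so the p-values with the preset rest on a lower correlation than was estimated and may be too small. The estimate takes in the unequal response of the Lck-cre samples (medians of 1.08, 0.53, 1.01 and 1.38 for called S phase genes in replicates 5 to 8). Most of the called lists share the adjusted p of 0.388, which the Benjamini-Hochberg adjustment gave them alike, so it does not rank them. How much of the loss of calls the higher correlation accounts for was not tested. Of 78 named calls besides Sting1, males alone and no filter ended 38 each, and TPM values, a pseudocount of 0.1 and quantile normalization 1 each. The planned count-based tests were not run, since the tables used here hold no counts. Without counts, the precision of values near 1 FPKM is unknown.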

Other observations

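The tests of scaling, segment length, rearrangement, shared reads, other cells, sample identity and mixture, and the splits of the samples, were chosen only after the results were seen. Of the list members below the filter, 3 passed with no filter. Cxcl10, a chemokine induced by interferons, rose from 0.0843 ± 0.0561 FPKM in the controls to 4.09 ± 3.23 FPKM in the Lck-cre samples (SD, n = 4 each, log2 change 2.63, adjusted p = 0.0494 by limma). Tbata, a gene of thymic epithelium, rose from 0.190 ± 0.0899 to 1.17 ± 0.486 FPKM (adjusted p = 0.0459 by limma), and Krt8, a keratin of epithelial cells, rose from 0.0642 ± 0.0316 to 0.2 ± 0.0437 FPKM (adjusted p = 0.0463 by limma). Bcl3, an NF-kB cofactor, did not pass, at 0.0315 ± 0.0365 and 1.28 ± 0.99 FPKM with no overlap (adjusted p = 0.0551 by limma). These genes were chosen after their values were seen.

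The response differed between Lck-cre samples. Relative to the mean of the 4, the change of Sting1 was 1.35, 0.47, 0.76 and 1.42 in replicates 5 to 8. The called interferon-stimulated genes had medians of 1.34, 0.29, 0.83 and 1.55, the called S phase genes 1.08, 0.53, 1.01 and 1.38, and the called ribosomal protein genes 0.85, 0.73, 1.5 and 0.93. With 4 samples no correlation was computed.

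Of the 35 splits of the 8 samples into 4 and 4, 1 gave as many genes as the 3180 of the real one, which was the real split. The highest other split gave 3. A rank of 1 in 35 is the strongest result possible here, so chance is not excluded. Every other split mixes the genotypes and puts their difference into the residual spread, so low counts there follow from the design. For the lists called by camera with the preset correlation, 1 of 35 splits gave as many as the 17 of the real one, again the real split, but the highest other gave 16. The number of lists called thus hardly sets the real split apart.

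The first pattern joined higher transcripts of replication genes with lower transcripts of distal TCR alpha segments in Lck-cre thymocytes. The rise of the S phase genes held under TPM, quantile and median-of-ratios values, with a lowest median log2 change of 0.641. These scalings moved the median of all tested genes by only -0.071 (TPM) and -0.02 (the others), so they could hardly have removed that rise. The alpha segments as a group were not examined under them. The short length of the J alpha segments is argued against, since the 26 nearest the constant gene lay lower than the 26 farthest from it. The median log2 difference was -1.182 (permutation p = 1e-05, the smallest possible), at median lengths of 60 and 62.5 bases. Across segments, which are not independent replicates, the J alpha change fell toward the constant gene (Spearman's rho -0.803, Pearson's r -0.809, and -0.786 without the 2 farthest segments) and the V alpha change rose toward the J cluster (rho 0.51, r 0.493, and 0.449), each with permutation p and adjusted p of 1e-05, the smallest possible, in a family of 6. V alpha segments with nearly the same values, such as Trav11d and Trav11, may share reads, which leaves the positions of the V alpha changes uncertain. The share of J alpha FPKM in the 26 J alpha segments nearest the constant gene was 50.7 ± 5.19% in the controls and 25.8 ± 7.23% in Lck-cre (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible). A candidate explanation is fewer secondary TCR alpha rearrangements per cell, since these join V and J segments ever farther apart, but a larger share of early, cycling cells within a gate that spans absent to intermediate TCR beta would leave the same trace and was not tested.

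The second pattern was the rise of gamma delta TCR and myeloid transcripts. Of 6 delta genes with a mean FPKM of at least 1, 5 rose and 0 fell, with a median log2 change of 0.713. The delta genes lie within the TCR alpha locus, and whether their rise shares a cause with the first pattern was not tested. Reads that move between the near-identical gamma constant genes would leave their sum alike, but the sum rose 6.52-fold, from 3.62 ± 1.82 to 23.6 ± 11.5 FPKM (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible). Whether gamma delta T cells in the fraction bring these transcripts cannot be told apart from transcription of the gamma genes in DP cells. Of the 15 list members that are not TCR genes, 2 were higher in all 4 Lck-cre samples than in all 4 controls. These were Gzma (21.0 and 65.5 FPKM) and Nkg7 (0.0485 and 0.574 FPKM), and the other 13 overlapped at means below 1 FPKM. The CD4 and CD8 gate is meant to exclude gamma delta T cells, but how well it did so was not tested. RNA of macrophages or dendritic cells may contribute, since 14 of 23 markers were higher in all 4 Lck-cre samples than in all 4 controls and 0 were lower, where chance gives 0.33. This 0.33 does not take into account that 29.4% of all tested genes did not overlap, in either direction. Of the 23 markers only 6 were tested, and the share among genes below the filter was not computed. The CD4 and CD8 gate is also meant to exclude macrophages and dendritic cells, but how well it did so was not tested. The levels were low, with Cd74 at 4.10 FPKM and Lyz2 at 0.560 FPKM in Lck-cre. RNA of thymic epithelial cells, some of which carry MHC class II, stays open and was not tested. Of their 15 markers 4 were higher without overlap, all 4 below the filter. The 29.4% is a share of tested genes in either direction, and the share among genes below the filter was not computed. The gate is meant to exclude epithelial cells as well, which was not tested either. Induction of such marker genes in the thymocytes by the genotype also stays open and was not tested. Ciita, a regulator of MHC class II genes, lay at 0.0981 ± 0.0387 FPKM in the controls and 0.111 ± 0.0272 FPKM in Lck-cre, with overlap. Its adjusted p by limma with no filter was 0.632, and levels this low do not decide.

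The third pattern was the place of Lck-cre replicate 6 nearest the controls. A mislabelled control is argued against, since its Sting1 level was 5.58 times that of the highest control. A share of cells without the induced allele would scale all lists alike, and the median relative response of this sample ranged by 0.46 between lists. That range does not decide, since another Lck-cre sample ranged by 0.82, so such a share and a weaker response of all cells cannot be told apart in bulk RNA. The difference between genotypes does not rest on this sample, since 3889 genes passed without it.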
